A study of Brachypodium distachyon with 9 samples.

How the data were processed

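RNA was sequenced from whole aboveground shoots of Brachypodium distachyon 21-3, a small temperate grass used as a model for cereals, at the 5-leaf stage. Per the labels' protocols, plants grew for 18 days with 14 h of light at 20 °C and 10 h of dark at 18 °C, then went 15 days without water under 16 h of light and 8 h of dark. Tissue was collected 3 h post dawn. The 3 genotypes were wild type, the CRISPR/Cas9 mutant gf14h-1, altered in the gene of the 14-3-3 protein GF14h, and the CRISPR/Cas9 mutant hdac19-2b, altered in the gene of HISTONE DEACETYLASE 19. Per the labels, both mutants are homozygous for an exon 1 mutation that gives a premature stop codon, and each genotype has 3 biological replicates. Libraries were made from TriReagent RNA after poly(A) selection, per the labels' protocols, so chloroplast transcripts and other RNA without a poly(A) tail are counted from what passed that selection.

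The authors deposited a table of estimated counts per annotated feature, where a feature is a RefSeq gene or a non-coding transcript. Between 69.1% and 83.2% of the values in a library were whole numbers to within 0.001, and the others were fractional, so its values were taken to be expected counts and rounded to whole numbers. The design fixed before the data were examined had assumed raw counts. The authors also deposited a normalized signal table, per its header a median ratio normalization with annotation. Multiplying it by 1 size factor per library gave whole reads, to within 0.1, for 99.9% to 100.0% of the values, and those reads served as an added alternative. It lacks 153 of the 28607 features of the count table. The submitters' processing notes name Partek, FastQC 0.11.9, HISAT2 and DESeq2. Their roles and settings, the counting program and whether counting used strand are not given in the sources used here. Reads from overlapping or antisense features, and from near-identical copies, can therefore not be told apart, and fold changes of such features are uncertain. This applies to rps19, rpl2, rps15, rps7, rpl23 and ndhB, which the chloroplast genome carries as inverted-repeat copies.

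Library totals ran from 3302835 to 36632994 counts. A floor of 3 counts in a library corresponds to 0.0819 to 0.908 CPM (counts scaled to a common library size). Folds against a group with 0 counts were computed against 3 counts over the summed libraries of that group and are lower bounds. Where a group held few counts, the ratio of pooled counts is given with its exact 95% interval. Intervals and floors cover counting error only.

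Differences were tested with edgeR 4.0.16 in R 4.3.3. A quasi-likelihood fit with genotype as the only term was made to all 9 libraries together, after TMM scaling and the default expression filter, which kept 23898 features holding 99.9% of counts. Values are given as TMM-scaled CPM, with the SD over 3 libraries, and as log2 fold changes with an approximate standard error (SE). The SE was derived from the test, as the absolute log2 fold change divided by the square root of the F statistic. P-values were adjusted with Benjamini-Hochberg, and features under 0.05 were called. Replicates were compared first. Within-group correlations of log2 CPM across features ran from 0.824 to 0.940 (median 0.924), and no pair of libraries agreed within sampling noise (chi-square per degree of freedom at least 18.0). The fit was tested on simulated counts for 23898 features. All simulated genotypes had the same spread per feature, and changes were planted only in features above a minimum abundance. The recovery therefore leaves out the larger spread among the gf14h-1 libraries and does not compare the power of the real comparisons. With gf14h-1 against wild type, it recovered 10.4%, 68.7% and 81.8% of features changed 2-, 4- and 8-fold. With hdac19-2b against wild type, it recovered 2.99%, 58.2% and 80.3%. In each simulation 7 unchanged features were called.

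Gene names came from the deposited annotation and from a RefSeq table of the assembly Brachypodium_distachyon_v3.0, which shares start positions with 98.5% of the deposited gene features. Of the features, 28606 matched a RefSeq symbol, but only 206 carried a gene name or a description beyond a locus number, and 159 of these were tested. Coordinates are 1-based on that assembly. GF14h and HDAC19 are not paired with a locus in the sources used here, so the transcripts of both targeted genes are not analysed here. Of 35 gene lists fixed before the data were examined, 5 had a member. These were NAC transcription factors, floral organ MADS-box genes, drought and abscisic acid response, cell wall growth, and iron and metal homeostasis, and the first 2 had at least 3 tested members. Another 22 lists were built on the symbols, descriptions and feature types of the annotation, after that annotation was seen and before any fold change. Of these, 20 could be tested. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and with Benjamini-Hochberg over 44 tests, and with an estimated correlation and fry beside it.

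The rule for named genes, fixed before the data were examined, took for each mutant against wild type the called features with a mean of at least 2 CPM, no overlap between the groups and a name or description, up to 10 in each direction. With fewer than 5 in a direction, it took the 5 smallest p-values, to be named as not past the threshold. It also took up to 3 called members of each list, and the 3 features called in both mutants with the largest change in each direction. Because most called features carry only a locus number, the 2 largest in each direction are named by locus as well, a choice made after the annotation was seen.

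Both mutants were compared with the same wild type libraries. All 9 libraries, wild type included, were therefore simulated 30 times without a genotype effect, to give the overlap and covariance that a shared wild type group brings. Each feature was drawn independently, with 1 mean and 1 spread for all genotypes. The unequal spread of the genotypes and any co-variation between features are thus left out. Lists of the observed lengths, ranked by p, were compared in the same simulations, a choice made after the overlap was seen. Alternatives fixed before the data were examined were DESeq2 size factors, no filter and a stricter filter, the DESeq2 1.42.0 Wald test, a replicate block, fits of only the 6 libraries compared, limma-trend on log2 of the normalized signal plus 1, a 2-fold minimum, and each library left out in turn. Counts summed per gene, the recovered reads and thinned libraries were added after the data were seen.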

Results

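The series measured transcript abundance by RNA sequencing in shoots of droughted Brachypodium distachyon, in wild type and in the mutants gf14h-1 and hdac19-2b, with 3 biological replicates each. GF14h is a 14-3-3 protein, a family that binds phosphorylated client proteins. HDAC19 is a histone deacetylase, an enzyme that removes acetyl groups from histones. Wild type libraries held 14837490, 12041696 and 36632994 counts for replicates 1, 2 and 3. The gf14h-1 libraries held 17653802, 15182384 and 3302835 counts, and the hdac19-2b libraries 17066545, 11135028 and 14568121. At least 1 count was seen for 23016 features in gf14h-1 replicate 3 and 24218 in gf14h-1 replicate 1, against 26072 to 27335 in the other libraries. Those gf14h-1 libraries also stood apart from the rest in a principal component analysis, replicate 3 on the first component (28.1% of the variance) and replicate 1 on the second. The mean variance of log2 CPM within a group was 1.07 in gf14h-1, 0.432 in wild type and 0.455 in hdac19-2b.

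The comparison of gf14h-1 with wild type asked which transcripts depend on GF14h in droughted shoots. The largest rise was in LOC112268938, a long non-coding RNA on chromosome 1 (17317420 to 17318853), which had 0 counts in all 3 wild type libraries and 43.5 ± 22.9 CPM (SD, n = 3) in gf14h-1, at least 689-fold higher. A further long non-coding RNA of chromosome 1, LOC104581633 (46687559 to 46690757), was likewise at 0 in wild type and reached 6.14 ± 4.64 CPM (SD, n = 3) in the mutant, at least 150-fold higher. The largest fall was in LOC100831965, a protein-coding locus of chromosome 3 (24296889 to 24305070), which went from 13.4 ± 0.254 CPM in wild type to 0 counts in all 3 gf14h-1 libraries, at least 165-fold lower. For LOC100828559, a protein-coding locus on chromosome 5, the values cover a non-coding transcript feature (25028160 to 25032473) and not the coding gene. That feature had 384 counts over the wild type libraries and 1 over the gf14h-1 libraries, a pooled ratio of 228 with a 95% counting interval of 40.7 to 9024. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment these 4 had adjusted p of 0.00255, 0.0284, 0.00255 and 0.0254.

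That test called 35 of 23898 features in gf14h-1, 16 higher and 19 lower, all with at least a 2-fold change. They comprised 30 features of protein-coding genes, 4 long non-coding RNAs and 1 pseudogene, the last 5 all higher in the mutant. In each of the 35 the mutant and wild type libraries did not overlap, which was so for 11.9% of all tested features and is so for 10% by chance with 3 against 3. The calls lay on chromosomes 1 to 5, with 8, 7, 11, 4 and 5 on each. At an unadjusted p under 0.05 there were 1807 features, where 1195 would be given by chance. Without wild type replicate 1, 2 or 3 the count was 8, 12 or 4. It was 20, 16 or 51 without gf14h-1 replicate 1, 2 or 3, and 7, 9 or 6 without hdac19-2b replicate 1, 2 or 3. The DESeq2 Wald test called 357, and a fit of only the 6 libraries called 4; LOC112268938 and LOC100831965 stayed past the threshold in every setting tried, LOC104581633 lost it without any library but gf14h-1 replicate 2 or 3, and LOC100828559 without any but wild type replicate 1 or gf14h-1 replicate 3 (Benjamini-Hochberg adjusted p 0.0559 to 0.107 in edgeR's quasi-likelihood test).

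None of the 159 tested features with a gene name or description passed edgeR's quasi-likelihood test in gf14h-1; 14 had an unadjusted p under 0.05, DESeq2 called 7 and limma-trend 0. Nearest to the threshold was LOC100828546 (chromosome 4, 47804128 to 47807070; synonym CIPK14), a kinase of the family that acts with calcineurin B-like calcium sensors. It stood at 43.2 ± 5.76 CPM in wild type and 95.9 ± 17.6 CPM in gf14h-1 (SD, n = 3), a log2 fold change of 1.15 (SE 0.21), with a Benjamini-Hochberg adjusted p of 0.0762 in edgeR's quasi-likelihood test. The abundant polyubiquitin genes LOC100832168 (UBQ4), at 675 ± 90.4 CPM in wild type and 1317 ± 231 in gf14h-1, and LOC100841406 (UBQ10), at 993 ± 167 and 1743 ± 415 (SD, n = 3), had log2 fold changes of 0.96 and 0.81. LOC100831269 (SAPK6), an SnRK2 kinase of the family that relays abscisic acid and osmotic signals, had 0.51, and the microRNA precursor MIR5175A had 1.73. Adjusted p in the same edgeR quasi-likelihood test with Benjamini-Hochberg were 0.183, 0.366, 0.579 and 0.685 for these 4, in that order. On the negative side, CBF7, a C-repeat binding factor of the AP2/ERF family, had a log2 fold change of −2.97 (SE 0.61) and CBF5 was at 0 counts in gf14h-1, at least 26.9-fold lower than in wild type. The chloroplast ribosomal protein genes rpl14, rps19 and rpl2 had −0.90, −1.61 and −1.02; the other inverted-repeat copies of rps19 and rpl2 had −0.50 and −0.96, with adjusted p of 0.942 and 0.519 in edgeR's quasi-likelihood test with Benjamini-Hochberg. CBF7, CBF5, rpl14, rps19 and rpl2 did not pass, with adjusted p of 0.129, 0.320, 0.252, 0.320 and 0.519 in that order from edgeR's quasi-likelihood test with Benjamini-Hochberg.

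The comparison of hdac19-2b with wild type asked the same of HDAC19. CBF7 (chromosome 4, 40903477 to 40904696) fell from 33.6 ± 28.2 CPM in wild type to 2.05 ± 0.814 CPM in hdac19-2b (SD, n = 3), a log2 fold change of −4.03 (SE 0.63). C-repeat binding factors activate genes of the cold and dehydration response. LOC100828546 (CIPK14) rose from 43.2 ± 5.76 to 99.5 ± 6.18 CPM (SD, n = 3), a log2 fold change of 1.20 (SE 0.20). It was higher in 3 of 3 mutant libraries than in any wild type library, which the rule for named genes required of called features. Benjamini-Hochberg adjusted p in edgeR's quasi-likelihood test were 0.0261 for CBF7 and 0.0425 for LOC100828546. These were the only 2 called among the 159 features with a name or description; limma-trend also called 2 and DESeq2 6. Wild type libraries differed widely in CBF7, at 65.6, 12.2 and 22.9 CPM in replicates 1, 2 and 3, and its call was lost without wild type replicate 1 or 3 or any hdac19-2b library (adjusted p 0.0735 to 0.182 in edgeR's quasi-likelihood test with Benjamini-Hochberg). That of LOC100828546 was lost without any of the wild type or hdac19-2b libraries (adjusted p 0.101 to 0.229 in that test), and over all its settings the adjusted p ran from 4.3e-07 to 0.229, against 2.5e-08 to 0.182 for CBF7.

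**Figure D1:**
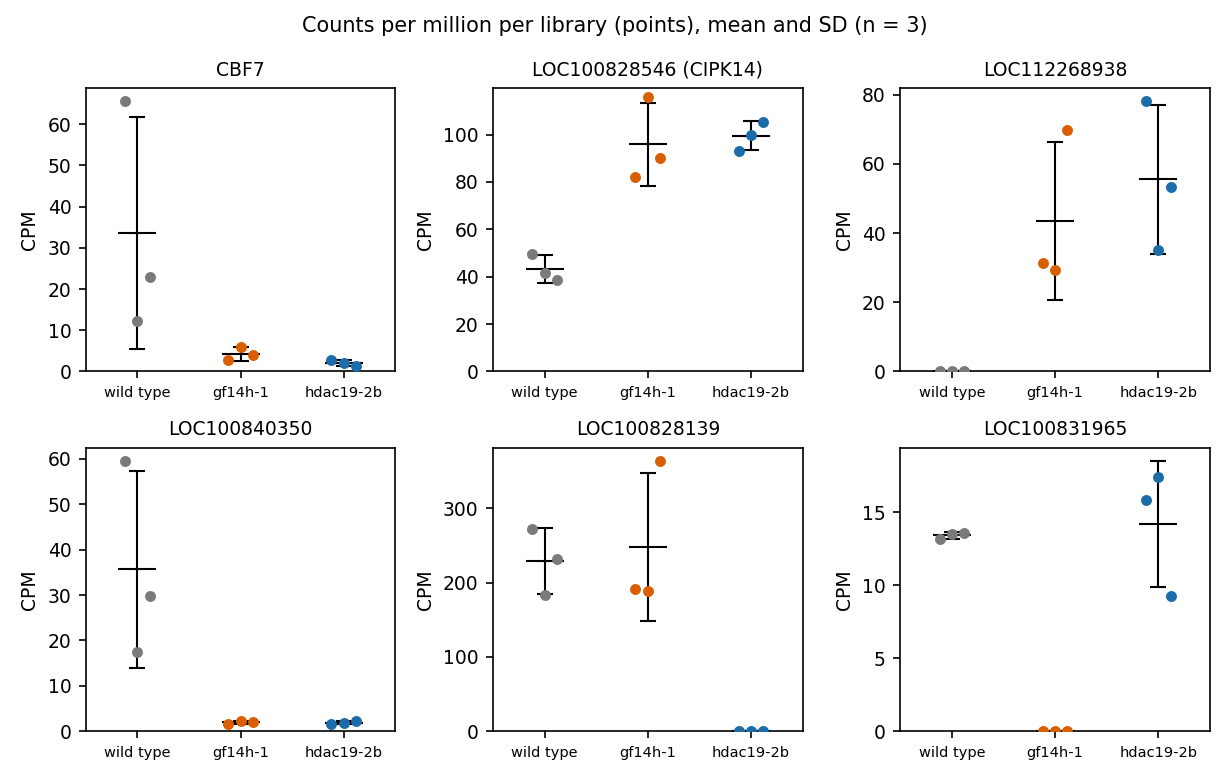
Abundance (TMM-scaled CPM, y axes from 0) of 6 features in the 3 genotypes; points are the libraries of replicates 1 to 3 from left to right, bars the mean and SD (n = 3), with the lower bar ending at 0 where the SD exceeds the mean. CBF7 and LOC100840350 were lower and LOC112268938 was higher in both mutants than in any wild type library, LOC100828139 was near 0 only in the hdac19-2b libraries and LOC100831965 was at 0 only in the gf14h-1 libraries.

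Among loci without a gene name, LOC100828139, a protein-coding locus of chromosome 4 (45565309 to 45567774), fell from 229 ± 44.0 CPM in wild type to 5 counts in hdac19-2b replicate 1 and 0 in replicates 2 and 3. The pooled ratio was 2076 (95% counting interval 889 to 6394), and the adjusted p in edgeR's quasi-likelihood test with Benjamini-Hochberg was 1.2e-04. LOC100834335 (chromosome 3, 40359281 to 40360482) fell from 64.9 ± 57.2 to 0.452 ± 0.288 CPM (SD, n = 3), a log2 fold change of −7.20 (SE 0.80). LOC112268938 rose in this mutant too, from 0 counts to 55.5 ± 21.5 CPM (SD, n = 3), at least 1197-fold. LOC112270984 on chromosome 2 (34069281 to 34072988) was at 0 counts in wild type and gf14h-1 and at 7.38 ± 1.20 CPM in hdac19-2b (SD, n = 3), at least 155-fold above wild type. The adjusted p of these 3 in the same edgeR quasi-likelihood test with Benjamini-Hochberg were 0.00841, 0.00187 and 0.0216. The call of LOC100834335 was lost without hdac19-2b replicate 1 (adjusted p 0.0682 in that test, 1.7e-20 to 0.0682 over all settings), and that of LOC112270984 without wild type replicate 1 or 3 or any hdac19-2b library (0.0602 to 0.147 in that test, 2.4e-09 to 0.147 over all settings).

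In all, edgeR's quasi-likelihood test called 65 features in hdac19-2b, 19 higher and 46 lower, again all with at least a 2-fold change and without overlap between the groups (16.8% of all tested features, 10% by chance). They comprised 59 features of protein-coding genes, 4 long non-coding RNAs, all higher, and 2 pseudogenes, 1 of them higher. Chromosomes 1 to 5 carried 14, 15, 17, 10 and 9 calls. At an unadjusted p under 0.05 there were 1719 features, against 1195 by chance. The count was 27, 91 or 9 without wild type replicate 1, 2 or 3. It was 108, 58 or 190 without gf14h-1 replicate 1, 2 or 3, and 2, 14 or 15 without hdac19-2b replicate 1, 2 or 3. It was 566 with the DESeq2 Wald test, 235 with only the 6 libraries and 152 with counts summed per gene.

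The other named genes that the rule took in hdac19-2b did not pass. The MAP kinase gene MPK3, whose family relays stress signals, stood at 101 ± 62.5 CPM in wild type and 26.9 ± 9.28 CPM in hdac19-2b (SD, n = 3), a log2 fold change of −1.90 (SE 0.44). CBF5 (chromosome 4, 40892649 to 40893643) had 2.60 ± 2.77 CPM in wild type and 0 counts in hdac19-2b, at least 32.9-fold lower. Log2 fold changes were −3.93 (SE 1.01) for the chloroplast gene rpl36, 4.27 (SE 1.11) for rps3 and 0.92 (SE 0.35) for rps15, whose other inverted-repeat copy had 0.34 (SE 0.40). They were −1.05 (SE 0.31) for LOC100834457, a sphingolipid delta(4)-desaturase DES1-like gene, 1.18 (SE 0.57) for LOC100841167, a MADS-box transcription factor 50-like gene, and 0.57 (SE 0.30) for the nucleoside diphosphate kinase gene NDPK3. In edgeR's quasi-likelihood test with Benjamini-Hochberg, adjusted p were 0.133 for MPK3, 0.188 for CBF5, 0.183 for rpl36, 0.185 for rps3, 0.512 for rps15, 0.269 for LOC100834457, 0.744 for LOC100841167 and 0.846 for NDPK3.

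Both mutants shared 20 calls, 12 higher and 8 lower, and none in opposite directions. Largest among those higher in both were LOC112268938, LOC104581633 (in hdac19-2b 2.31 ± 0.196 CPM, at least 47.3-fold above wild type) and LOC112269290, a pseudogene on chromosome 5 (2549231 to 2552042) at 0 counts in wild type, at least 150-fold higher in gf14h-1 and at least 124-fold in hdac19-2b. Largest among those lower in both were LOC100834335, with log2 fold changes of −5.37 in gf14h-1 and −7.20 in hdac19-2b, LOC100823053, with −6.13 and −5.52, and LOC100840350, with −4.22 and −4.28. LOC100823053 lies on chromosome 2 (33398110 to 33399971) and LOC100840350 on chromosome 4 (46817829 to 46821277). In edgeR's quasi-likelihood test with Benjamini-Hochberg, adjusted p in gf14h-1 and hdac19-2b were 0.0284 and 0.0245 for LOC104581633, 0.0394 and 0.0230 for LOC112269290, 0.0284 and 0.00841 for LOC100834335, 0.0335 and 0.0216 for LOC100823053, and 0.0104 and 0.00841 for LOC100840350. In hdac19-2b, LOC104581633, LOC112269290 and LOC100823053 lost the threshold without wild type replicate 1 or 3 or any hdac19-2b library, and LOC100840350 without hdac19-2b replicate 1 (0.0635 to 0.142 in that edgeR quasi-likelihood test with Benjamini-Hochberg). In gf14h-1, LOC100840350 held whichever library was left out, but lost the threshold in 2 of its 17 settings. By contrast, LOC100823053 lost the threshold without any but wild type replicate 2, LOC100834335 without any but wild type replicate 2 or gf14h-1 replicate 3, and LOC112269290 without any but gf14h-1 replicate 1 or 3 (0.0538 to 0.172 in that edgeR quasi-likelihood test with Benjamini-Hochberg).

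Since both comparisons use the same wild type libraries, some overlap arises without any effect. Of the 35 calls in gf14h-1, 33 had the same sign in hdac19-2b, and of the 65 calls in hdac19-2b, 63 had the same sign in gf14h-1. In libraries simulated without an effect and with a shared wild type group, the 35 and 65 features with the smallest p gave 30 to 35 and 55 to 64. These counts lay within what the simulations give. Those simulated lists shared on average 6.93 features in the same direction and at most 11, against the 20 observed. Simulated calls were almost absent, on average 0.0667 and 0.167 per mutant, and so could share almost nothing (0.0333 higher and 0 lower). Independent lists of the observed lengths would share 0.0127 higher and 0.0366 lower. Across all 23898 features, which are not independent replicates, the 2 sets of log2 fold changes had a correlation of 0.399 (0.484 simulated), the same sign in 60.2% (66.3% simulated) and a covariance of 0.305, against a simulated mean of 0.252 and a simulated maximum of 0.267. The difference in covariance was 0.0524, and part or all of the excess overlap may come from the shared wild type libraries, which are too few to split. The count shared by both mutants was 5, 9 or 2 without wild type replicate 1, 2 or 3. It was 11, 8 or 30 without gf14h-1 replicate 1, 2 or 3, and 1, 5 or 4 without hdac19-2b replicate 1, 2 or 3. The DESeq2 Wald test gave 165, counts summed per gene 37 and fits of only the libraries of each comparison 3.

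**Figure D2:**
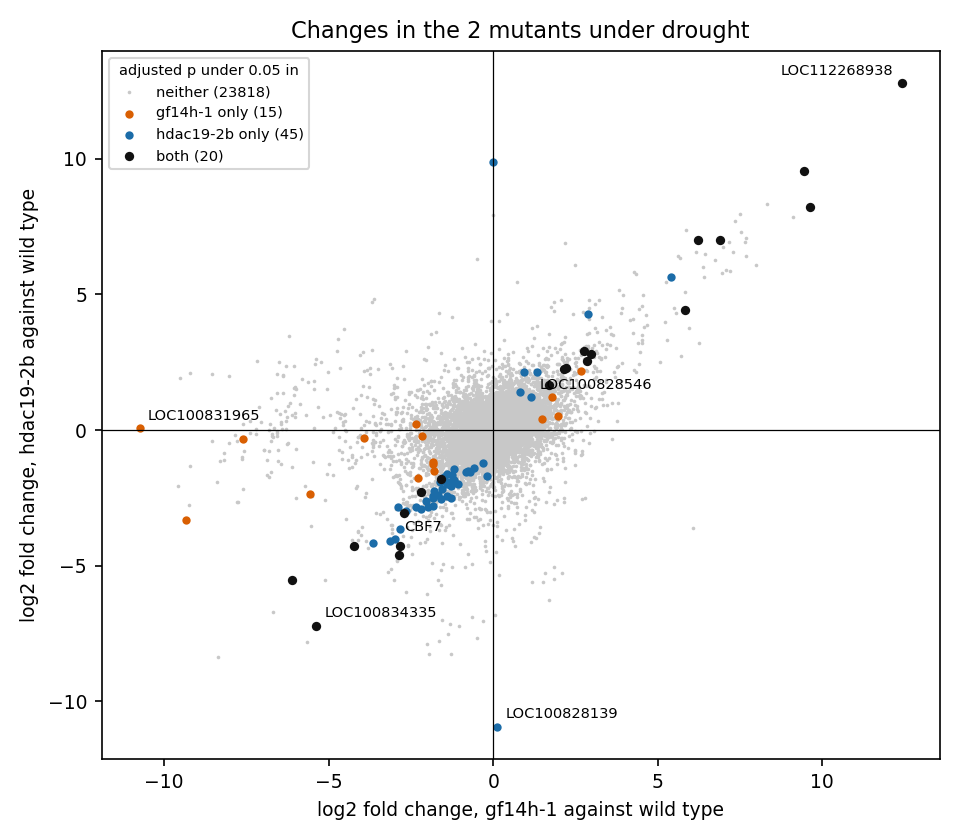
Log2 fold change of each of 23898 tested features in gf14h-1 (x axis) and hdac19-2b (y axis), both against the same 3 wild type libraries; colours mark features called in neither mutant, in gf14h-1, in hdac19-2b or in both. The 20 features called in both lie in the upper right (12) and lower left (8) quadrants; fitted values of features with 0 counts in a group depend on the prior count.

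The direct comparison of gf14h-1 with hdac19-2b tested whether the mutants' effects differed. LOC100828139 was far lower in hdac19-2b, where it was nearly silent, than in gf14h-1, at 248 ± 99.9 CPM (SD, n = 3). Conversely, LOC100831965 was at 0 counts in gf14h-1 and at 14.2 ± 4.33 CPM in hdac19-2b (SD, n = 3). A pair of protein-coding loci on chromosome 5 was lower in gf14h-1 than in both other genotypes. LOC100826926 (16196159 to 16201127) stood at 11.1 ± 4.64 CPM in gf14h-1, 69.5 ± 17.2 in hdac19-2b and 59.0 ± 6.90 in wild type, and LOC100821161 (13331775 to 13339322) at 12.3 ± 3.68, 46.5 ± 4.62 and 54.1 ± 4.08 (SD, n = 3). Against wild type they had log2 fold changes of −2.35 and −2.18 in gf14h-1, with adjusted p of 0.0254 and 0.0104 in edgeR's quasi-likelihood test with Benjamini-Hochberg. These 4 were the features called between the mutants, 1 higher and 3 lower in gf14h-1, with adjusted p of 1.1e-04, 0.00160, 0.0313 and 0.0313 in that order from edgeR's quasi-likelihood test with Benjamini-Hochberg. At an unadjusted p under 0.05 there were 2157 features, against 1195 by chance. The count was 2 without wild type replicate 2 or 3, gf14h-1 replicate 1 or hdac19-2b replicate 1, 7 without gf14h-1 replicate 2, 282 with the DESeq2 Wald test and 1 with only the 6 libraries. The differences of LOC100826926 and LOC100821161 lost the threshold without any library but gf14h-1 replicate 3 (Benjamini-Hochberg adjusted p 0.0586 to 0.195 in edgeR's quasi-likelihood test). That of LOC100831965 lost it only in the fit of the 6 libraries (Benjamini-Hochberg adjusted p 0.0817 in edgeR's quasi-likelihood test). Against wild type, the fall of LOC100821161 was lost without wild type replicate 3, and that of LOC100826926 without any wild type library, gf14h-1 replicate 2, or hdac19-2b replicate 1 or 3 (0.0611 to 0.107 in that edgeR quasi-likelihood test with Benjamini-Hochberg). Over all settings, the fall of LOC100821161 was lost in 3 of 17 and that of LOC100826926 in 8 of 17. For CBF7 and LOC112270984 the mutants did not differ past the threshold (adjusted p 0.658 and 0.154 in edgeR's quasi-likelihood test with Benjamini-Hochberg).

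No gene list moved as a group past the threshold in either mutant. Of 44 list tests with camera, 5 had an unadjusted p under 0.05 and none an adjusted p under 0.05; the lowest adjusted p was 0.209, against 0.910 with an estimated correlation and 0.111 with fry. In hdac19-2b, 8 of the 9 SnRK2 kinase genes had negative log2 fold changes (median −0.11), as had 12 of 14 features of the abscisic acid core, which adds protein phosphatases 2C and the transcription factor TRAB1 (camera adjusted p 0.209 for both lists). No member of either list was called in that mutant; LOC100823438 (SAPK2) had −0.72 and LOC100843625 (SAPK5) −0.74. In gf14h-1, 7 of the 9 SnRK2 genes had positive values (median 0.18, camera adjusted p 0.417). Chloroplast ribosomal protein genes had negative values for 16 of 24 features in gf14h-1 (camera adjusted p 0.209), with 2 lower when adjusted over the list alone and 0 over all features. The share of counts from the chloroplast was 0.873% in wild type replicate 1, 1.57% and 1.61% in wild type replicates 2 and 3, and 0.885% to 1.47% in the mutant libraries. Without wild type replicate 1 this list had a camera adjusted p of 0.00376, and 7 list tests passed, 6 of them chloroplast lists lower in a mutant and 1 of them small nucleolar RNAs higher in gf14h-1. Without gf14h-1 replicate 2 the ribosomal protein list had an adjusted p of 0.0497 with camera. Of 4 genes of calcineurin B-like sensors and their kinases, LOC100828546 was called in hdac19-2b, and 1 was higher in each mutant when adjusted over the list alone.

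Of the lists fixed before the data were examined, the 7 NAC transcription factors, all annotated as secondary wall NAC genes or their like, had no call in either mutant, neither over all features nor adjusted over the list alone. Their median log2 fold changes were 0.46 in gf14h-1 and 0.21 in hdac19-2b (camera adjusted p 0.551 and 0.538). The floral organ MADS-box list held 3 tested genes, all described as AGL62-like, a type I MADS-box kind not among the floral organ identity genes, and had 0 calls, also adjusted over the list alone (camera adjusted p 0.712 and 0.417). In gf14h-1 its median of 0.15 was positive and its mean of −0.21 negative. Median, mean and camera direction also differed in sign for all MADS-box factors, flowering time MADS-box genes, calcineurin B-like sensors and their kinases, microRNA precursors and long non-coding RNAs in gf14h-1, and for flowering time MADS-box and chloroplast ATP synthase genes in hdac19-2b. The lists with a single member gave log2 fold changes in gf14h-1 and hdac19-2b of 0.18 and −0.31 for LOC106865379 (SAPK1, drought and abscisic acid response), −2.62 and −0.83 for the expansin-B6-like gene LOC100843684 (cell wall growth) and 0.04 and −0.45 for YSL9 (iron and metal homeostasis). None of these was called in edgeR's quasi-likelihood test, in which the lowest Benjamini-Hochberg adjusted p among them was 0.618, for LOC100843684 in gf14h-1. All 44 list medians but those of the MAP kinase cascade and of the flowering time MADS-box genes in gf14h-1, both near 0, kept their sign with DESeq2 size factors.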

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

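The tests of the lost features were chosen after the result was seen. For 4 features the effects of gf14h-1 and hdac19-2b against wild type differed in the direct test between the mutants, and they are given here for that reason. The difference in log2 fold change, gf14h-1 minus hdac19-2b, was 11.04 for LOC100828139 and −10.82 for LOC100831965, fitted values that depend on the prior count because a group is at or near 0 counts. It was −2.58 for LOC100826926 and −1.96 for LOC100821161.

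LOC100831965 was lost in gf14h-1 alone and LOC100828139 in hdac19-2b alone. A deleted stretch of chromosome would take neighbours with it. The 10 neighbouring tested features, some of them of the same locus, had median log2 fold changes of 0.0481 around LOC100831965 and −0.0431 around LOC100828139. This argues against a deletion that reaches them. The nearest tested neighbours ended at 24195969 and started at 24331196 around LOC100831965, and at 45563291 and 45569321 around LOC100828139. A lesion between these positions, loss of the whole gene included, stays open for both. Reads moved to a near-identical copy stay open: without regard to any test, 1884 features had a mean CPM in gf14h-1 above both other genotypes by at least 50% of the CPM lost at LOC100831965, and 13 did so in hdac19-2b for LOC100828139, none of them called against both, so such a copy cannot be told apart from the spread between libraries. A sequence variant carried by the line at the locus itself and an effect of the GF14h or HDAC19 mutation both stay open and were not tested.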

How the results depend on the processing

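Counts summed per gene, recovered reads and thinned libraries were tests chosen after the data were seen. With gf14h-1, hdac19-2b, the direct comparison and the calls shared by both mutants in that order, the counts of 35, 65, 4 and 20 became 357, 566, 282 and 165 with the DESeq2 Wald test. They became 4, 235, 1 and 3 with only the 6 libraries compared. Counts summed per gene gave 152 for hdac19-2b and 37 shared. With each library left out in turn the counts ran from 4 to 51, 2 to 190, 2 to 7 and 1 to 30. The number of lists past the threshold ran from 0 to 7 over those fits, with 7 without wild type replicate 1. It was 1 without the filter, where the list of 3 C-repeat binding factors was lower as a group in hdac19-2b. For all of these, and for the replicate block, the cause was not tested. Replicate numbers did not pair the libraries: same-numbered libraries had deviation correlations of −0.136 to 0.0204 over 9 pairs, and 0 of 9 libraries correlated best with their own number. With a replicate block the counts were 4, 12, 2 and 2. The other scaling, the stricter filter, limma-trend and thinning of all libraries (medians of 26, 85, 4 and 20) kept each count within 1.5 times. The recovered reads gave 35, 65, 4 and 20, but they equalled the rounded counts in at least 99.997% of values per library. The 2-fold minimum left the counts as they were because every call had at least a 2-fold change. Neither of these settings could therefore test the counts. Of 24 called values of named features, 5 stayed past the threshold in every setting, 19 lost it in at least 1 and 0 reversed; of 38 not called, 11 passed in a setting. The depth of gf14h-1 replicate 3 limits what can be seen there, since 3 counts correspond to 0.908 CPM.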

Other observations

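The splits into 3 and 6, the covariance and both thinning tests were planned before their results were seen. The tests of features silent in a genotype, of ranked lists of fixed length, of the order of the wild type libraries, and of the covariance given by the wild type spread were chosen after results were seen. Many features that were lower in hdac19-2b also varied in step among the wild type plants. Of the 46, 27 (58.7%) were highest in wild type replicate 1 and lowest in wild type replicate 2, against 18.7% of all tested features, and the median ratio of replicate 1 to replicate 2 was 1.77, against 1.01 over all. CBF7 was among them, at 65.6, 12.2 and 22.9 CPM in wild type replicates 1, 2 and 3, and MPK3, which was not called, had the same order at 170, 48.6 and 83.3 CPM. Of the 19 features lower in gf14h-1, 8 had that order, and of the 8 lower in both mutants, 5. The library code of wild type replicate 1 starts with HS and those of all other libraries with HJ. Whether these prefixes mark a difference between the libraries was not tested.

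All 20 features called in both mutants differed from wild type in the same direction. Between wild type and the 6 mutant libraries, 91 features were called, 22 higher and 69 lower in the mutants. Of the 84 splits of the 9 libraries into 3 and 6, only the real one called as many, and the highest other called 4. A share of 1 in 84 is the smallest these splits can give, so it argues against chance but does not exclude it. Most other splits mix genotypes, which widens the spread within their groups, so the gap between 91 and 4 is no measure of the evidence. Chance values of the wild type libraries as the whole cause stay open. The covariance of 0.305 lay above the simulated maximum of 0.267, and 20 calls were shared against at most 11 in simulated lists of the same lengths. The covariance of log2 CPM differences was 0.223 against 0.144 from the wild type spread, a value without a range. The simulation drew features independently, whereas many features lower in hdac19-2b varied in step among the wild type plants. Its ranges are therefore too narrow to decide. The correlation (0.399, at least 0.464 simulated) and the share of equal signs (60.2%, at least 65.8% simulated) lay below the simulated values and give no such excess, nor do the signs of the called features. A difference in depth is argued against by 92 calls (median of 5 draws) after thinning. A candidate explanation that stays open is that the wild type plants differ in genomic background from both lines, which may leave features silent in wild type or in both mutants: 6 features were present in every library of one side and silent in the other (4 silent in wild type, 2 in the mutants), and 2 of the 84 splits had as many, the other being gf14h-1 against the rest with 7. An effect that both mutations share stays open as well and was not tested.

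Fewer features were called in gf14h-1 (35) than in hdac19-2b (65), a difference in counts that was not itself tested. The low depth of gf14h-1 replicate 3 was weighed by thinning hdac19-2b replicate 3 to it. This left 64 calls (median of 5 draws), so a single library of that depth would not by itself lower the count to 35. Without gf14h-1 replicate 3 in the fit, the counts were 51 for gf14h-1 and 190 for hdac19-2b. In fits of only the 6 libraries compared, where the spread is not shared with the third genotype, the counts were 4 for gf14h-1 and 235 for hdac19-2b. The counts of 35 and 65 thus depend on the spread pooled over all genotypes. The larger spread among the gf14h-1 libraries (mean variance of log2 CPM 1.07, against 0.455 in hdac19-2b) stays open as a cause, as does a smaller effect of the mutation. For each comparison of 3 libraries with 3, the 10 splits are too few for a share under 0.05. The real split was the 1 with the most calls in each, with 35 for gf14h-1 against wild type, 65 for hdac19-2b against wild type and 4 between the mutants, and the highest of the other splits gave 0 in each. All other splits mix genotypes, which widens the spread within their groups, so these gaps are no measure of the evidence.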
